A study of Mus musculus with 11 samples.

How the data were processed

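Single-cell 3' RNA libraries (10x Genomics v3.1 chemistry) were made from immune cells sorted from mouse atheromas, the plaques of the aortic root, arch and aorta that form on an atherogenic diet. CD45.1 and CD45.2 are variants of the leukocyte surface protein encoded by Ptprc, and the cells carrying each were sorted apart and sequenced apart, per the labels' protocols. The 11 libraries held 7 of WT cells, 2 of Dnmt3a KO cells and 2 of Tet2 KO cells. All 5 CD45.1 libraries were WT, while the CD45.2 libraries were the 4 knockout libraries and 2 WT libraries of 24 weeks. There were 5 libraries of 30 weeks (replicate 1 of each group) and 6 of 24 weeks. WT cells are written here as WT-D, WT-T or WT-W for the Dnmt3a, Tet2 or WT condition they were sorted from. By Xist and Y-linked transcripts, both libraries labelled Tet2 KO, Dnmt3a KO 1 and WT-W 2 were male and the other 7 libraries mainly female, of which the 3 of 30 weeks also held Y-linked transcripts. Sex thus went with genotype at 30 weeks. The titles of WT-W 2 and Tet2 KO 2 carry a mark f whose meaning the labels do not give. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

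The deposited matrices held counts: whole-number unique molecular identifiers (UMIs) per gene and cell barcode, not normalised. They were made with Cell Ranger 6.1.2 on mm10, per the submitters' processing notes. The headers of the 24-week matrices give version 6.1.1, and those of the 30-week matrices give none. The authors' 24-week files listed 32285 genes and their 30-week files 28692, so the gene annotation differed with the week. The annotation releases are not given in the sources used here. Genes were joined on the Ensembl identifier, which left 27734 genes, 1228 of them under different symbols in the 2 annotations. Between 99.1% and 99.5% of each library's UMIs were joined. Coordinates came from GENCODE vM21 on GRCm38 (mm10), which held 27657 of the joined genes. The counting is not stated to use strand, so a gene that overlaps another on the opposite strand is uncertain.

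The files held 49344 barcodes with 10080922 to 45789248 UMIs per library. Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. Doublets were scored per library against simulated doublets, and the highest-scoring cells were removed at a rate of 0.8% per 1000 cells, which took out 1697. The 45206 cells kept had a median of 2115 to 4173 UMIs per library at 30 weeks and of 4036 to 6857 at 24 weeks. The smallest barcode held 1237 to 1738 UMIs in the 30-week files and 500 to 502 in the 24-week files, a difference in the authors' cell calling that can set shares of small cells. Cells were clustered on 2000 variable genes centred within each week, 30 principal components and 15 neighbours with the Leiden method at resolution 1 (igraph 0.11.9, leidenalg 0.10.2), which gave 37 clusters. Clusters were named X-like from marker lists fixed beforehand, with at least 3 markers detected in 25% of cells and read against the 10 leading genes. The scoring rule was set after the clusters were seen, and 8781 cells stayed unnamed: 3.92% to 8.63% of each 30-week library and 13.0% to 36.5% of each 24-week library. The macrophage-like class held 9161 cells, which were clustered again into 18 subclusters. Most 30-week macrophages lay in cluster 0 and most 24-week macrophages in cluster 3, so week is a term in every fit that holds both.

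Raw UMI counts were summed over the macrophage-like cells of each library and tested with edgeR 4.0.16 (quasi-likelihood F test, TMM normalisation, filterByExpr) in R 4.3.3, with terms for genotype, week and sorted fraction over all 11 libraries. Adjusted p-values follow Benjamini and Hochberg over all genes tested, with a threshold of 0.05. The term for the sorted fraction rests on the WT libraries of 24 weeks alone, since they are the only WT libraries with both fractions. A fold for a gene that differs between those fractions therefore leans on 4 libraries. CPM, the UMIs of a gene scaled to a common library total, was computed from the deposited counts in 2 ways: "normalised CPM" uses TMM library sizes of the macrophage sums, and "plain CPM" uses the UMI total of the cells named. WT cells of each condition were compared in the same way with a term per group, and the 7 WT libraries were compared by week. Shares of cells were tested with edgeR on cell numbers. Other classes were tested where a library had at least 20 cells. Gene lists were tested with camera (limma 3.58.1) at its preset correlation, again with an estimated correlation, and with fry, over 36 lists and both knockouts. The lists named in the text are inflammatory cytokines and chemokines, inflammasome, NF-kB response, interferon response, MHC class II presentation, Trem2 foam cell programme, resident macrophage programme, cholesterol efflux and LXR targets, cholesterol synthesis, complement, alternative activation, glycolysis, hypoxia, NRF2 and heme response, cell cycle, immediate early and dissociation, heat shock, and markers of B cells, T cells and plasma cells.

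The designs, gene lists, markers, cell filters, rule for named genes and most alternatives were fixed before the data were examined. The rule for a knockout names Dnmt3a, Tet2 and Ptprc, then up to 10 called genes with the highest and 10 with the lowest fold among those with an average log2 CPM of at least 3, without sex-linked, mitochondrial, immunoglobulin and T-cell receptor genes and unnamed gene models. Where fewer than 10 genes were called it adds those of smallest p to make 10. For other contrasts it names the 5 highest and 5 lowest called genes by the same filter, for lists up to 4 members of smallest p, and for other classes the 3 called genes of smallest p. Alternatives were DESeq2 1.42.0 (size factors, and its own Wald test), no filter on low counts, no doublet removal, macrophages picked by markers alone, sums thinned to the smallest library, other covariates, other sets of WT libraries and each library left out in turn. Further alternatives were added after seeing the data. They were the sex of the cells as a term, 24-week libraries only, macrophages without mixed or single-library clusters, and macrophages without resident-like subclusters. Intervals are exact 95% Poisson or binomial intervals and cover counting error only.

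The fits were tested on simulated counts with 200 changed genes in each of 3 simulations. With the spread of the mean trend, the Dnmt3a KO comparison of 11052 genes recovered 48.1% of 2-fold and 89.5% of 4-fold changes, with 4.74% of calls false. With gene-specific spread these values were 44.1%, 84.9% and 9.24%, so the false share then exceeded the threshold. For the Tet2 KO comparison they were 55.7%, 90.6% and 3.53% with the trend, and 51.4%, 84.7% and 10.9% with gene-specific spread. For the comparison of WT cells between conditions they were 45.2%, 79.7% and 2.91%, and 34.8%, 78.4% and 6.96%. For the comparison of weeks they were 57.4%, 87.1% and 4.81%, and 50.9%, 90.5% and 11.5%. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest. Fibroblast-like and plasma-cell-like cells were too few for a test of genes. The values of 1 member of the complement list are not reported here.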

Results

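Immune cells from atherosclerotic plaques of mice were profiled by single-cell RNA sequencing, with cells labelled Dnmt3a KO or Tet2 KO set against WT cells at 24 and 30 weeks. Dnmt3a encodes an enzyme that adds methyl groups to DNA, and Tet2 one that oxidises them. Both are genes that are often mutated in clonal haematopoiesis. There were 11 libraries: 7 of WT cells, 2 of Dnmt3a KO cells and 2 of Tet2 KO cells, with 1 library of each knockout at each week. WT cells are written WT-D, WT-T and WT-W for the Dnmt3a, Tet2 and WT conditions they were sorted from. Replicate 1 is the 30-week library and replicates 2 to 4 are 24-week libraries. The libraries held 10080922 to 45789248 UMIs, and 45206 cells were kept, of which 9161 were macrophage-like. Macrophage-like cells per library ranged from 86 (WT-T 1) to 1619 (Dnmt3a KO 1), with 404008 to 10786071 UMIs summed over them. Most 30-week macrophages lay in cluster 0 (4940 of its 5048 cells) and most 24-week macrophages in cluster 3 (3385 of its 3386 cells).

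The targeted genes were read first, in plain CPM of the macrophage-like cells. Dnmt3a (chromosome 12, 3806007 to 3914443, GRCm38, GENCODE vM21) stood at 16.5 in Dnmt3a KO 1 (95% Poisson interval 13.7 to 19.7), against 39.7 ± 8.80 in WT macrophages of 30 weeks (SD, n = 3). It stood at 40.2 in Dnmt3a KO 2 (35 to 46), against 94.2 ± 22.9 in WT macrophages of 24 weeks (SD, n = 4), and at 41.4 and 76.0 in the libraries labelled Tet2 KO. Tet2 (chromosome 3, 133463679 to 133545139) was not lower in the libraries labelled Tet2 KO. It stood at 44.3 at 30 weeks, against 17.3 to 22.7 in WT libraries, and at 54.9 at 24 weeks, against 52.1 to 68.2. In the Dnmt3a KO libraries Tet2 stood at 22.6 and 73.3. Ptprc (chromosome 1, 138062861 to 138175708), which encodes CD45, ranged from 233 to 272 at 30 weeks and from 465 to 572 at 24 weeks over all genotypes. The deleted part of each gene is not given in the sources used here, and 3' tags outside it check nothing. Neither fold passed the test: Dnmt3a in Dnmt3a KO macrophages had a log2 fold of -1.25 ± 0.26 (SE, adjusted p = 0.0784) and Tet2 in macrophages labelled Tet2 KO one of 0.45 ± 0.31 (adjusted p = 0.946), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

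The comparison of Dnmt3a KO with WT macrophages asked which transcripts differ in plaque macrophages of that genotype. Dnmt3a KO macrophages carried more RNA of C2, a complement protease, and of BC018473, an uncharacterised transcript annotated antisense to a neighbour. C2 was at 50.8 and 36.4 normalised CPM in the 2 Dnmt3a KO libraries and at 0.516 ± 0.457 in WT (SD, n = 7), a log2 fold of 7.56 ± 0.63 (SE, adjusted p = 3.42e-04). BC018473 was at 61.4 and 105 against 0.379 (log2 fold 7.399 ± 0.38, adjusted p = 3.12e-06). The pooled ratio of UMIs was 88.6 for C2 (95% interval 54.8 to 153) and 163 for BC018473 (102 to 282). Apoc1, a lipoprotein component, was at 52.3 against 3.37 ± 1.49 (3.83 ± 0.49, adjusted p = 0.00830), and Lzts2 at 16.9 against 2.11 (3.24 ± 0.29, adjusted p = 4.49e-04). Kitl, the ligand of the receptor Kit, was at 32.3 against 15.1 ± 7.20 (1.76 ± 0.22, adjusted p = 0.00694). Runx3, a transcription factor of lymphocytes and myeloid cells, fell from 82.7 ± 16.7 to 27.4 (-1.34 ± 0.19, adjusted p = 0.0161). St6galnac2, a sialyltransferase, rose from 3 pooled WT UMIs to 17.4 normalised CPM (ratio 206, 69.6 to 1006, adjusted p = 9.66e-04). In all, 13 genes rose and 2 fell of 11052 tested, and 1018 had an unadjusted p under 0.05.

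The folds of 3 called genes that lean on the term for the sorted fraction are given here with and without it. Other called genes may lean on it in part. Kitl had a fitted fold of 3.38 with means of 32.3 and 15.1 normalised CPM. Its 24-week WT libraries held 12.3 and 15.25 in CD45.2 (WT-W 2 and 4) and 28.9 and 19.5 in CD45.1 (WT-D 2 and WT-W 3). The fitted fold was 189 for C2 and 415 for St6galnac2, against pooled UMI ratios of 88.6 and 206. The small heat-shock protein gene Hspb1 was at 88.6 and 30.3 normalised CPM in Dnmt3a KO macrophages and at 34.8 in WT, but at only 4.14 and 4.77 in the WT CD45.2 libraries. Its log2 fold was 3.30 ± 0.52 (adjusted p = 0.0420, edgeR with Benjamini-Hochberg adjustment) and 0.69 without the term (adjusted p = 0.836). With 24-week libraries only its fold was 0.03 (adjusted p = 0.998). The metallothionein gene Mt2 was at 184 against 109, with 1.57 ± 0.26 (adjusted p = 0.0430) and 0.78 without the term (adjusted p = 0.360). Mzb1, which B-lineage cells use in antibody assembly, was at 7.43 and 44.2 against 3.93, with 5.90 ± 0.96 (adjusted p = 0.0430) and 3.05 without the term (adjusted p = 0.106). The remaining called genes were Ighm (2.14 ± 0.26, adjusted p = 0.00605), Igkc, Tpm2, Mxra7 (2.50, adjusted p = 0.0334) and Trbc2, a T-cell receptor gene (-2.72 ± 0.45, adjusted p = 0.0448).

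Leaving out 1 library in turn kept the calls of C2, BC018473, Apoc1 and Lzts2 in all 11 fits, but each of the 4 lost its call in at least 1 of the other alternatives. With CD45.2 libraries only, the adjusted p was 0.0940 for C2, 0.358 for Apoc1, 0.0898 for Lzts2 and 0.0264 for BC018473, by edgeR with Benjamini-Hochberg adjustment. With macrophages picked by markers it was 0.0662, 0.747, 0.474 and 0.00225, in the same order. Thinning to the smallest library ended the calls of C2 (0.193), Apoc1 (0.122), Kitl (0.194) and Hspb1 (0.0529). Apoc1 also lost its call without doublet removal (0.179) and with WT libraries of the WT condition only (0.140). Runx3 lost its call in 4 of the 15 alternatives other than leaving out a library. With 24-week libraries only, Mzb1 (0.120), Mt2 (0.510), Kitl (1.06, 0.258) and St6galnac2 (0.0561) were not called either. Where a knockout library is left out, the lone one is assumed to vary like the other groups. Without Dnmt3a KO 2, Mzb1 (adjusted p = 0.410), Kitl (0.0826), Mt2 (0.450), Runx3 (0.293) and St6galnac2 (0.265) lost their call by edgeR. Mzb1, Hspb1 and Mt2 lost theirs without WT-D 1 (0.0759, 0.0726 and 0.0798), without WT-T 1 (0.0914 each) and without WT-W 4 (0.0765, 0.0627 and 0.0814). Mzb1 and Hspb1 lost theirs without WT-W 2 (0.0911 each), and Mzb1 alone without WT-D 2 (0.0580) or WT-W 1 (0.0544). The 15 calls became 8 without Dnmt3a KO 2, 9 without WT-T 1, 26 without WT-W 3, 35 without WT-W 2, 37 without Tet2 KO 2, 39 without Tet2 KO 1 and 45 without Dnmt3a KO 1.

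**Figure D1:**
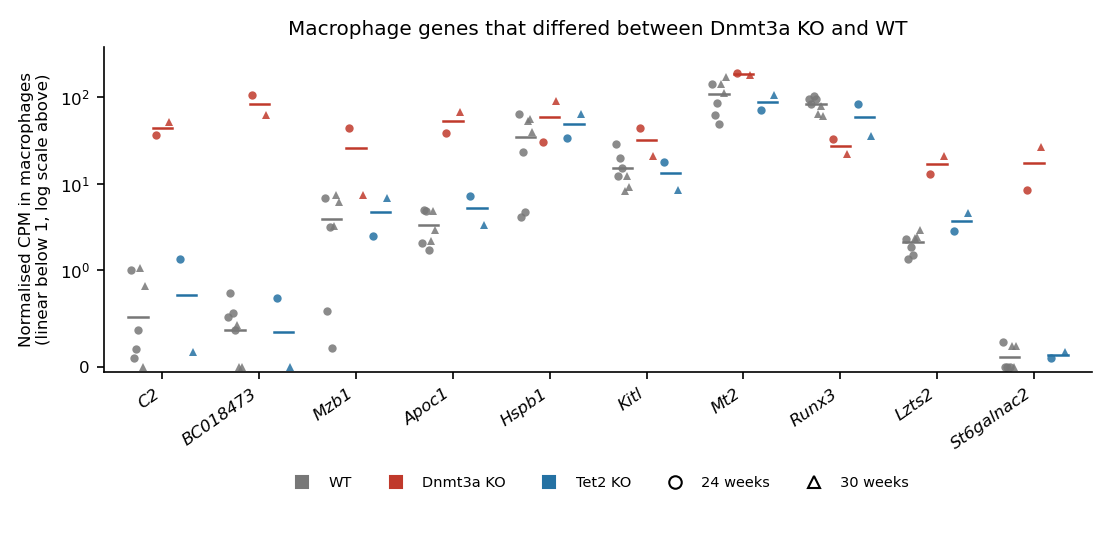
Normalised CPM (log-like axis, linear near 0) of the 10 named genes in macrophage-like cells, with a point per library and bars at the group means. C2 and BC018473 lie at or above 36.4 in both Dnmt3a KO libraries and near 0 in WT.

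Of the called genes, 3 lie close together on chromosome 11 (GRCm38): St6galnac2 at 116675303 to 116694868, BC018473 at 116752167 to 116759373 and Mxra7 at 116803062 to 116828046. Cygb, which encodes cytoglobin, lies at 116645595 to 116654313 and had a log2 fold of 3.14 ± 0.61 that was not called (adjusted p = 0.0633, edgeR with Benjamini-Hochberg adjustment). Within 200 kb of BC018473, 10 genes were tested, 7 of them with a positive fold and 3 called. The other named genes lie elsewhere: C2 on chromosome 17 (34862604 to 34898265), Apoc1 on 7 (19689481 to 19692660), Kitl on 10 (100015630 to 100100416), Runx3 on 4 (135120652 to 135177990) and Lzts2 on 19 (45014414 to 45027111). The sources used here do not state whether the counting used strand, so reads of BC018473 and of a gene on the other strand may not have been told apart.

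By gene list, markers of B cells and the resident macrophage programme were higher in Dnmt3a KO macrophages, and markers of T cells lower, by camera at its preset correlation (adjusted p = 3.06e-20, 4.04e-11 and 1.31e-16 over 72 list tests). None of these held with an estimated correlation: the adjusted p was 0.274 for B-cell markers, 0.473 for the resident macrophage programme and 0.274 for T-cell markers. All 9 B-cell markers tested were positive and all 9 were called when adjusted over the list alone, among them Ms4a1 (log2 fold 4.86), Pax5 (4.46), Ebf1 (3.18) and Ighm, with Ighm alone called over all genes. Of the T-cell markers 13 of 14 were negative, with 10 called when adjusted over the list alone (Cd8a -4.02, Trbc1 -3.15, Cd3d -2.95) and Trbc2 over all genes. Named T cells were also fewer, at 1.02% and 10.9% of the Dnmt3a KO libraries against 28.3% on average in WT. Macrophage subcluster 15, led by Trbc1, Trbc2 and Rag1, held 0.432% and 0.181% of Dnmt3a KO macrophages and 0.762% to 3.08% of WT macrophages. The fall of T-cell markers therefore cannot be parted from T cells or their RNA within the macrophage class. The resident macrophage programme, genes typical of long-lived tissue macrophages, had 20 of 20 positive (median 1.15). Adjusted over the list alone, 3 of them were called: Ninj1 (0.87), Gas6 (1.33) and Cd209g (2.80). Folr2 had 1.63, and none of the 20 was called over all genes.

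Heat shock had 13 of 13 positive and 5 called when adjusted over the list alone (Hspb1, Hsph1 1.15, Bag3 1.10 and Dnaja1 0.70 among them), with a camera adjusted p of 7.67e-09 and an adjusted p = 0.274 with an estimated correlation. The NRF2 and heme response had 12 of 15 positive and 4 called over the list alone (Mt2, Slc40a1 2.42, Hmox1 1.11, Mt1 0.97), at 1.11e-05, with adjusted p = 0.473 with an estimated correlation. Of the plasma-cell markers 5 of 6 were positive, with Iglc2 (7.91), Jchain (3.77), Tnfrsf17 (2.93) and Mzb1 higher and Sdc1 (-2.09) lower over the list alone, at 4.67e-05, with adjusted p = 0.274 with an estimated correlation. MHC class II presentation had 9 of 11 negative (H2-DMb1 -0.77, H2-Eb1 -0.68, Ctss -0.46, but H2-Ob 0.91) at 7.24e-04, and the Trem2 foam cell programme 17 of 20 (Gpnmb -1.35, Spp1 -0.99, Lpl -0.45, but Fabp4 2.06) at 5.51e-04, with no member called in either. Both had adjusted p = 0.506 with an estimated correlation. Complement (9 of 10 positive, C4b 1.08, C3 0.81), NF-kB response (13 of 15, Ier3 0.64, Nfkb1 0.62) and hypoxia (10 of 16, Egln3 2.78, Adm 1.65, Hilpda 0.74) were called at 0.0166, 0.0315 and 0.0392, with no member called. Their adjusted p was 0.506, 0.506 and 0.541 with an estimated correlation. Inflammatory cytokines and chemokines were not called (adjusted p = 0.681). Of these, 10 of 24 were positive, the median was -0.06, the mean 0.05 and the test's direction down, and Il12b (-2.24), Tnfsf9 (-0.93) and Cxcl16 (-0.49) were lower over the list alone, with Il1b at -0.81 not called. Nor were the inflammasome (adjusted p = 0.646) or cholesterol efflux and LXR targets (0.283). The latter hold Apoc1 and Scd1 (1.79), both called over the list alone, and had an adjusted p of 4.88e-04 in fry's mixed test, which asks whether members change in either direction.

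Some list calls rested on single libraries. Without Dnmt3a KO 1 the Trem2 foam cell programme (adjusted p = 0.319), complement (0.124) and NF-kB response (0.0758) were no longer called by camera. Without Dnmt3a KO 2 the same held for NF-kB response (0.213), hypoxia (0.442) and the markers "other cells: plasma cell" (0.104). Without WT-W 2 NF-kB response (0.518) and hypoxia (0.822) lost their call, without WT-W 4 the Trem2 foam cell programme (0.0583) and complement (0.634), and without WT-D 2 NF-kB response (0.0624).

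The comparison of macrophages labelled Tet2 KO with WT asked the same of Tet2. Ly6a (chromosome 15, 74994877 to 74998031), which encodes the interferon-inducible surface protein Sca-1, was the 1 gene called of 11052, and 697 had an unadjusted p under 0.05. It stood at 517 and 385 normalised CPM in the libraries labelled Tet2 KO and at 116 in WT (n = 7), a log2 fold of 1.64 ± 0.19 (SE, adjusted p = 0.0248, edgeR with Benjamini-Hochberg adjustment). The Dnmt3a KO libraries averaged 261. The genes of next smallest p were not called. The complement factor C3 was at 43.2 against 13.2 (1.94 ± 0.27, adjusted p = 0.0521) and the complement inhibitor Cd55 at 8.52 against 1.56 (3.15 ± 0.49, 0.0797). Mmp9, a matrix-degrading protease, was at 26.0 against 5.94 (2.89 ± 0.52, 0.151), and Hspb1 at 48.5 against 34.8 (3.05 ± 0.51, 0.0949, and 0.50 without the term for the sorted fraction). Lower values were those of Gdpd3, a lysophospholipase D (7.85 against 23, -1.75 ± 0.24, 0.0521), the chemokine Cxcl14 (8.94 against 38.8, -1.94 ± 0.31, 0.0797) and the pro-apoptotic gene Bik (4.62 against 15.1, -1.47 ± 0.23, 0.0797). Mcub, a subunit of the mitochondrial calcium channel (84.2 against 141, -0.95 ± 0.15, 0.0797), and Zmynd15 (26.7 against 109, -1.50 ± 0.25, 0.0954) were lower too.

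The count of 1 was fragile. It became 101 without the term for the sorted fraction and 0 with 24-week libraries only, CD45.2 libraries only, or WT libraries of the WT condition only. Ly6a lost its call by edgeR without Tet2 KO 2 (adjusted p = 0.285), WT-T 1 (0.104), WT-W 1 (0.0983) or WT-W 4 (0.0537), with 24-week libraries only (0.371) and with CD45.2 libraries only (0.472). It also lost its call without doublet removal (0.0838), with macrophages picked by markers (0.249), with WT libraries of the WT condition only (0.267) and without resident-like subclusters (0.0785). With macrophages picked by markers the log2 folds of Cxcl14, Bik and C3 shrank to -0.25, -0.33 and 0.68 (adjusted p = 1 each). The count was 0 without WT-T 1, WT-W 1 or WT-W 4, 2 without WT-D 1, WT-D 2 or Tet2 KO 2, 4 without Tet2 KO 1, 8 without Dnmt3a KO 2, 9 without Dnmt3a KO 1 and 91 without WT-W 2. Gdpd3, C3 and Cxcl14 gained a call without Dnmt3a KO 1 (0.0191, 0.0368 and 0.0368), Dnmt3a KO 2 (0.0194, 0.0346 and 0.0346) or WT-W 2 (0.0340, 0.0340 and 0.00225), and C3 without WT-D 1 (0.0463). Hspb1 and Mmp9 gained one without Dnmt3a KO 1 (0.0368 and 0.0191) or Dnmt3a KO 2 (0.0346 and 0.0194), and Hspb1 without WT-D 2 (0.00205). Mmp9 and Cd55 gained one without Tet2 KO 1 (0.0174 each), Zmynd15 without Tet2 KO 2 (0.0265), and Cd55, Bik, Mcub and Zmynd15 without WT-W 2 (0.0419, 0.0340, 0.0419 and 0.0344).

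**Figure D2:**
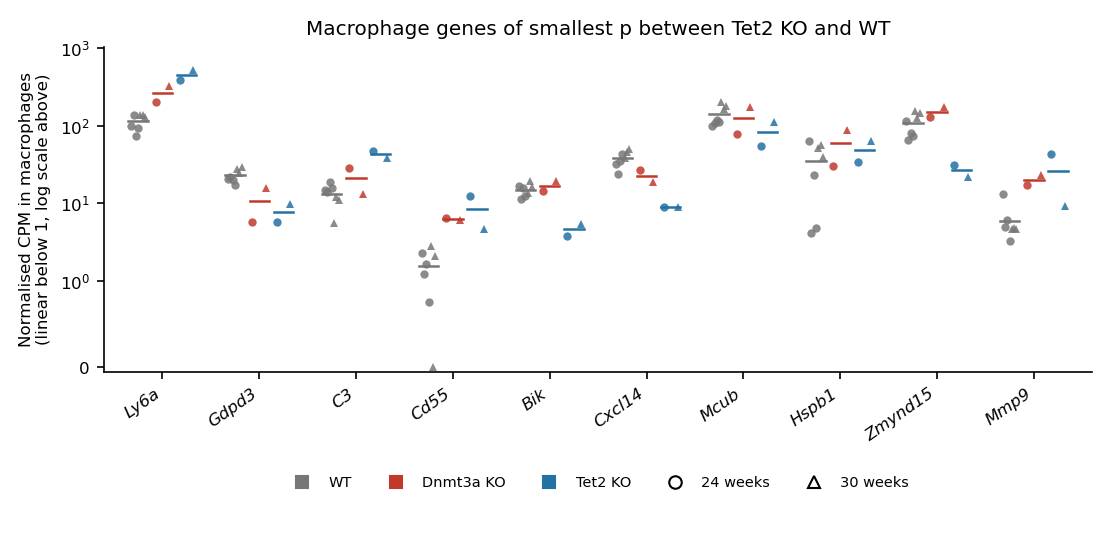
Normalised CPM (log-like axis, linear near 0) of the 10 named genes in macrophage-like cells, with a point per library and bars at the group means. Ly6a was at 517 and 385 in the libraries labelled Tet2 KO, against a WT mean of 116.

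By gene list, the resident macrophage programme, interferon response and complement were higher in macrophages labelled Tet2 KO, by camera at its preset correlation (adjusted p = 2.34e-18, 1.81e-14 and 1.06e-09). None held with an estimated correlation (adjusted p = 0.289, 0.274 and 0.274). All 20 resident genes were positive and 9 were called when adjusted over the list alone (Cd209g 3.05, Cd209f 2.76, Gas6 1.22, Selenop 0.97). All 24 interferon genes were positive with 8 called over the list alone (Ifi44 1.33, Ifit2 0.84, Oasl2 0.76, Irf7 0.72). All 10 complement genes were positive with 4 called over the list alone (C3, Cfb 1.35 and Cfp 0.61 among them). None of these members was called over all genes. Of the B-cell markers 9 of 9 were positive, with 7 called over the list alone (Ms4a1 2.98, Ighd 1.35, Ighm 0.91), and of the plasma-cell markers 4 of 6, with 2 called (Mzb1 3.55, Tnfrsf17 2.69). Their camera adjusted p was 1.07e-10 and 7.24e-04, and the adjusted p was 0.274 and 0.346 with an estimated correlation. The marker lists "other cells: B cell" and "other cells: plasma cell" were not called without the term for the sorted fraction (adjusted p = 0.0880 and 0.201).

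Further lists were called for Tet2 at the preset correlation with few or no members called. Immediate early and dissociation genes had 18 of 18 positive (Klf2 0.77, Jun 0.72, adjusted p = 3.35e-04), with adjusted p = 0.506 with an estimated correlation. Heat shock had 12 of 13 positive (Hspb1 called over the list alone, 3.63e-04), with adjusted p = 0.489 with an estimated correlation. Alternative activation had 10 of 13 positive (Cd209d 1.91, called over the list alone, Clec10a 1.49, but Arg1 -3.01, 0.00688), with adjusted p = 0.274 with an estimated correlation. Cell cycle had 20 of 20 negative (Ube2c -1.33, Mki67 -0.97, adjusted p = 0.0010), with adjusted p = 0.637 with an estimated correlation. The Trem2 foam cell programme had 14 of 20 negative (Cd9 -0.72, Spp1 -1.06 and Syngr1 -0.95 called over the list alone, 0.00157), with adjusted p = 0.506 with an estimated correlation. T-cell markers had 12 of 14 negative (Trbc2 -1.21, 0.00654), with adjusted p = 0.536 with an estimated correlation. Glycolysis had 15 of 18 negative (Slc16a3 -0.98, Aldoa -0.36, 0.00688) and cholesterol synthesis 12 of 15 (Msmo1 -0.55, 0.0435), both with adjusted p = 0.506 with an estimated correlation. Inflammatory cytokines and chemokines (16 of 24 positive, adjusted p = 0.0648), the inflammasome (0.316) and cholesterol efflux and LXR targets (0.333) were not called. Leaving out WT-W 4 ended the calls of the Trem2 foam cell programme (0.0609), alternative activation (0.0846), cell cycle (0.802), cholesterol synthesis (0.946), glycolysis (0.859) and immediate early and dissociation (0.880). Leaving out Tet2 KO 2 ended those of alternative activation (0.106), cell cycle (0.0811), cholesterol synthesis (0.973) and glycolysis (0.165), Tet2 KO 1 those of heat shock (0.0630) and "other cells: T cell" (0.323), and WT-W 2 that of "other cells: T cell" (0.831). Cholesterol synthesis also lost its call without WT-D 1 (0.0547), Dnmt3a KO 1 (0.0649), WT-T 1 (0.0526), WT-D 2 (0.0639) or Dnmt3a KO 2 (0.0546). The list of inflammatory cytokines and chemokines gained one without WT-T 1 (0.0310), WT-W 2 (0.0387), WT-W 3 (0.0312) or Tet2 KO 2 (2.63e-05).

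Macrophages of both knockouts were compared directly, since the series title speaks of their likeness. Of 11052 genes, 27 were higher and 7 lower in Dnmt3a KO than in macrophages labelled Tet2 KO. Among those with an average log2 CPM of at least 3, leaving out unnamed gene models, the highest were BC018473 (log2 difference 7.61 ± 0.38, adjusted p = 2.13e-06), C2 (5.55 ± 0.46, 2.20e-04), Apoc1 (3.26 ± 0.43, 0.00869) and Zmynd15 (2.45 ± 0.25, 0.00137), then the LIM-domain gene Crip2 (1.94 ± 0.24, 0.00614). Zmynd15 was at 152 normalised CPM in Dnmt3a KO and 26.7 in macrophages labelled Tet2 KO. The lowest by the same filter were Spon1 (-1.91 ± 0.34, 0.0439), Runx3 (-1.04 ± 0.18, 0.0372), Tlr1, a receptor for bacterial lipopeptides (-1.01 ± 0.18, 0.0430), Fgl2 (-1.01 ± 0.17, 0.0342) and Clec2d (-0.79 ± 0.13, 0.0369), all by edgeR with Benjamini-Hochberg adjustment. The count of 34 became 8 without Tet2 KO 2, 12 without Tet2 KO 1, 16 without WT-W 1, 17 without Dnmt3a KO 2, 19 without WT-D 1, 152 without WT-W 4 and 155 without WT-W 2.

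The log2 folds of both knockouts correlated across the 11052 genes at r = 0.438, where genes are not independent replicates. Unchanged groups simulated against the same WT libraries gave 0.543 ± 0.021 (SD over 20 simulations). The covariance was 0.132, against 0.118 ± 0.00714 in the simulations with a highest value of 0.128. The share of genes with the same sign was 60.6%, against 68.4% simulated. With the WT libraries split so that each knockout had its own, r was 0.141, the covariance 0.0575 and the same-sign share 53.3%. At an unadjusted p under 0.05, 151 genes were higher in both (671 and 402 in each, 24.4 for independent lists) and 57 lower in both (347 and 295, 9.26), where the first number in each bracket is the Dnmt3a KO list. The shared WT libraries alone gave 69.95 ± 8.52 genes higher in both (highest 90) and 62.6 ± 8.89 lower in both (highest 81) in 20 simulations without any change. The simulated lists were shorter, with 242.7 and 240.8 genes higher and 260.9 and 254.55 lower on average. The 57 genes lower in both thus did not exceed what the shared libraries alone gave. The 151 higher in both lay above the highest simulation, but longer lists share more genes, so the simulations cannot decide this count. Part or all of them may come from the shared libraries. The correlation was 0.260 without Dnmt3a KO 1, 0.220 without Tet2 KO 1 and 0.700 without WT-W 2.

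**Figure D3:**
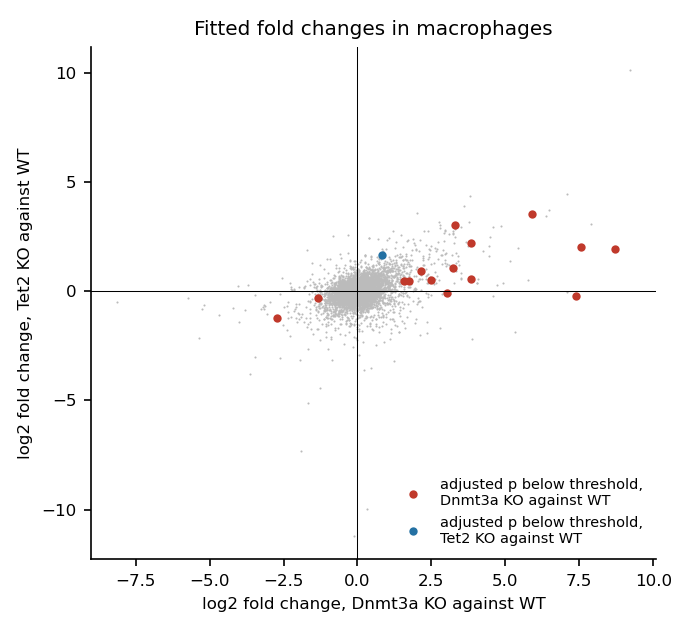
Log2 fold against WT of each gene in Dnmt3a KO macrophages (x axis) and in macrophages labelled Tet2 KO (y axis), with genes called for Dnmt3a KO in red and for Tet2 KO in blue. C2, BC018473 and Apoc1 lie far to the right, at 7.56, 7.399 and 3.83.

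Whether WT macrophages differ with the knockout cells beside them was asked of WT cells of the knockout conditions. Between WT-D and WT-W macrophages edgeR called 0 of 11682 genes, with 291 at an unadjusted p under 0.05, and DESeq2's Wald test called 0. Between WT-T 1, a single library of 86 macrophages, and WT-W edgeR called 0, with 840 at an unadjusted p under 0.05, the lone library being assumed to vary like the other groups. Between Dnmt3a KO macrophages and the WT-D macrophages of the same condition edgeR called 0, with 474 at an unadjusted p under 0.05, while DESeq2's Wald test called 8 genes. The count of 0 does not show a lack of difference: BC018473 was at 0.432 and 0.512 normalised CPM in WT-D 1 and 2 and at 61.4 and 105 in Dnmt3a KO 1 and 2 (log2 difference 6.69 ± 1.64, SE, edgeR adjusted p = 1). C2 was at 1.08 and 1.02 and at 50.8 and 36.4 (6.51 ± 1.62, adjusted p = 1). The edgeR count of 0 became 9 without the term for the sorted fraction, 4 without Dnmt3a KO 1 and 1 without WT-W 2.

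WT macrophages of 24 weeks differed from those of 30 weeks in 4794 of 10724 genes, 2692 higher and 2102 lower, with 5623 at an unadjusted p under 0.05. The resident-macrophage receptor gene Vsig4 was at 0 to 7.02 normalised CPM at 24 weeks (n = 4) and 86.4 to 295 at 30 weeks (n = 3), a log2 fold of -6.24 ± 0.86 (adjusted p = 3.14e-04). The B-cell chemokine Cxcl13 was at 0 to 20.8 and 171 to 1486 (-6.44 ± 1.42, 0.00458). Tonsl (-6.67 ± 0.19, 2.52e-08), the phosphatase gene Ptp4a1 (-6.69 ± 0.37, 1.53e-06) and Srp54c (-6.72 ± 0.26, 1.87e-07) were also lower at 24 weeks. Rnasek was higher at 24 weeks (0 to 0.864 at 30 weeks, 232 to 269 at 24, log2 fold 8.40 ± 0.23, 2.17e-08), and so was the cytokine gene Tnfsf13 (at most 0.216, then 53.0 to 90.3, 6.82e-07). Galnt2 was at 0 in all 30-week WT libraries and 29.2 to 35 at 24 weeks, Cpne1 at 0 and 15.6 to 22.3, and Srp54a at 0 and 8.19 to 17.9. Srp54a and Srp54c are near-identical copies and the annotation differed with the week, so their values are uncertain. Transcripts of heart muscle, named after their values were seen, also went with the week. The atrial hormone gene Nppa was at 12.1, 13.1 and 154 normalised CPM in the 30-week WT libraries, highest in WT-T 1, and at 0 in all 24-week WT libraries. The myosin light chain gene Myl7 was at 12.6 to 115 and 0. Week is confounded with the gene annotation, the cell calling and the depth, and the adjusted p-values are edgeR's. Of 95 genes with an absolute log2 fold of at least 5, 58 of 62 tested in T cells, 50 of 52 in B cells and 48 of 48 in monocytes had a log2 fold of the same sign and at least 50% of the size there. Among 1925, 1821 and 1895 other genes, only a part of those tested in these classes, the shares were 78.8%, 89.7% and 92.4%.

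Cell classes were compared for their share of each library. Plasma cells were 2.33% and 4.93% of the Dnmt3a KO libraries of 30 and 24 weeks and 0.827% ± 0.882 of the WT libraries (SD, n = 7), and were the 1 class called (log2 fold 4.05 ± 1.25, adjusted p = 0.0420, edgeR with Benjamini-Hochberg adjustment). At 30 weeks WT-T 1 had 2.09%, WT-W 1 had 2.13% and Tet2 KO 1 had 1.87%. Cells named T cells were 28.3% ± 12.5 of WT libraries, 1.02% and 10.9% of Dnmt3a KO libraries (adjusted p = 0.573) and 11.9% and 11.6% of libraries labelled Tet2 KO. Clusters 2, 5 and 15, in which T-cell markers were the most widely detected, stayed unnamed and lay almost wholly at 24 weeks. They held 531, 612 and 408 cells of Tet2 KO 2, beside 677 named T cells. In WT-W 2 they held 1381, 323 and 158, beside 722, and in Dnmt3a KO 2 108, 4 and 20, beside 478. The shares of named T cells at 24 weeks therefore depend on the naming rule. Macrophages were 57.1% of Dnmt3a KO 1, 41.1% of Tet2 KO 1 and 2.50% to 36.0% of WT libraries at 30 weeks, and 12.6%, 18.0% and 9.15% to 17.3% at 24 weeks. The sort and the authors' cell calling can set such shares. The plasma-cell call was kept without Dnmt3a KO 1 (adjusted p = 0.0112) or WT-T 1 (0.00941) and lost without WT-D 1 (0.0778), Tet2 KO 1 (0.0723), WT-W 1 (0.0711), WT-D 2 (0.0613), Dnmt3a KO 2 (0.726), WT-W 2 (0.549), Tet2 KO 2 (0.0723), WT-W 3 (0.0642) or WT-W 4 (0.454). A two-sided exact permutation of genotype within week gave p = 0.05 (adjusted p = 0.533). That is the smallest p its 20 arrangements can give, so it could not call the class.

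Within macrophages, cells named resident-like from markers such as Lyve1, Folr2 and Cbr2 made up 18.5% and 15.3% of Dnmt3a KO macrophages at 30 and 24 weeks. They made up 27.3% and 8.16% of macrophages labelled Tet2 KO, and 3.47% ± 1.85 of WT macrophages (SD, n = 7, 1.04% to 5.97%). Foamy-like cells averaged 13.4% in WT, 9.53% in Dnmt3a KO and 8.87% in libraries labelled Tet2 KO, interferon-like cells 2.92%, 2.46% and 5.86%, and subcluster 4 made up 9.70%, 6.80% and 12.4%. That subcluster was led by the stress and immediate early genes Hspa1a, Dnajb1, Jun, Fos and Atf3 beside the chemokine genes Ccl3 and Ccl4, so it is given by number. Cavity-like cells averaged 3.77%, 3.61% and 2.74% and cycling cells 4.93%, 4.52% and 3.69%. edgeR called 0 of these state shares: the resident-like log2 folds were 2.22 ± 0.83 for Dnmt3a KO and 2.24 ± 0.87 for Tet2 KO (adjusted p = 0.111 each, Benjamini-Hochberg). At an unadjusted p under 0.05, 3 of the 12 share tests passed. The markers that name these cells are also in the resident macrophage programme, so the share and that list are not independent. They were 2.32 and 2.35 without the term for the sorted fraction, where both were called (adjusted p = 0.00924). A two-sided exact permutation within week gave p = 0.05, the smallest of 20 arrangements, for the resident-like and foamy-like shares of both knockouts and for the interferon-like share of Tet2 KO (adjusted p = 0.12 each). With 24-week libraries only, the Dnmt3a KO fold was 2.33 and called (adjusted p = 0.0287), and the Tet2 KO fold 0.61 and not called (0.468). Both were called without WT-W 2 (0.0143) or Tet2 KO 2 (0.0140), and the Dnmt3a KO share without Tet2 KO 1 (0.0280). From 35.1% to 66.0% of each library's macrophages fell in subclusters that stayed unnamed. One of these, subcluster 12 with Cd163, Lyve1, Mmp9 and Cd209f among its leading genes, held 10.8% of the macrophages of Tet2 KO 2, 6.05% in WT-W 2 and 0 to 0.943% in the others.

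**Figure D4:**
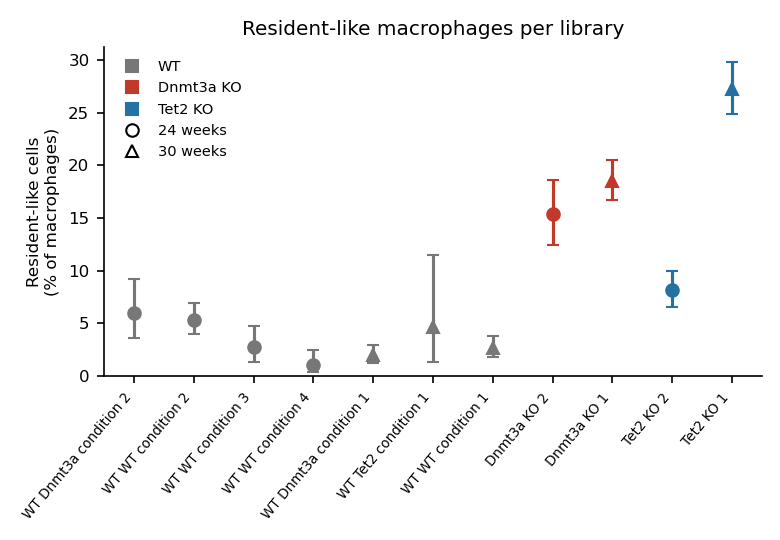
Percent of macrophage-like cells named resident-like in each library, with exact 95% binomial intervals that cover counting error only. The 4 knockout libraries lie between 8.16% and 27.3% and the 7 WT libraries between 1.04% and 5.97%.

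In other cell classes, B cells had the most genes called in Dnmt3a KO libraries, with 615 genes higher and 463 lower of 9379 by edgeR. Of B-cell cluster 7, 79.5% of the cells came from Dnmt3a KO 2 (1471 cells), so the B cells compared were not spread alike over clusters. Krt8, an epithelial keratin gene, was at 222 and 248 plain CPM in Dnmt3a KO B cells and had 1 UMI over all WT B cells against 3677 (ratio 3969, 712 to 156820, adjusted p = 1.58e-08). Gnb3 (ratio 260, 119 to 709, adjusted p = 1.19e-06) and Gng13 (225, 109 to 561, 2.68e-06), which encode G-protein subunits, rose as well. B cells labelled Tet2 KO had 12 genes called, led by AC168977.1 (log2 fold 2.66 ± 0.30, edgeR adjusted p = 0.00191), C130026I21Rik (1.68, 0.00815) and Fgl2 (2.26 ± 0.34, 0.0161). AC168977.1 and C130026I21Rik are among the leading genes of B-cell cluster 17. That cluster held 231 of 776 B cells of Tet2 KO 1 and 224 of 304 of Dnmt3a KO 1. It held 108 of 660 in WT-D 1, 171 of 1309 in WT-T 1 and 72 of 367 in WT-W 1. A shift between B-cell clusters therefore cannot be told apart from a change within B cells. ILC2 cells, innate lymphocytes that make type 2 cytokines, had 17 genes called in Dnmt3a KO, among them Il13 (5.53 ± 0.79), S100a8 (5.72) and Ccl5 (-5.35, adjusted p = 0.0208 each). NK cells had 25 called in Dnmt3a KO (BC018473 9.36, Plac8 2.30, Il7r -2.77) and 40 in Tet2 KO (Klra3 -2.03, Spp1 2.57, Xist), and neutrophils 5 in Dnmt3a KO (BC018473, Igkc 5.94, Ighm 5.53). NK cells and neutrophils were tested at 24 weeks with 1 knockout library each and 2 residual degrees of freedom, so these calls set that library against WT and have no replicate check. Tet2 KO 2 was male by transcripts and 3 of the 4 WT libraries female, which Xist follows. ILC2 cells for Tet2 and migratory DCs for Dnmt3a KO also had 1 knockout library, assumed to vary like the others. Monocytes had 4 called in Dnmt3a KO (BC018473 6.76, C2 5.38, Ube2c 3.16), cDC1 cells 6 (Cd79a 7.69, Igkc 4.59, Ly6d 4.36) and cDC2 cells 1 (BC018473 7.51). Cd79a and Ighm are on the B-cell marker list, Igkc is an immunoglobulin gene and S100a8 is on the neutrophil list. Their calls in cDC1 cells, neutrophils and ILC2 cells cannot be told apart from RNA of other cells. For Tet2, cDC1 cells had 2 called (Cxcl9 3.27, Mcub -2.32). edgeR called 0 genes for Tet2 in ILC2, cDC2, monocytes and neutrophils (116, 168, 291 and 107 at an unadjusted p under 0.05), and 0 in T cells (290 for Dnmt3a KO and 368 for Tet2 KO) and migratory DCs (193 and 190). With the title mark f as a term the Dnmt3a KO counts were 694 in B cells, 96 in NK cells, 36 in neutrophils, 10 in monocytes, 8 in migratory DCs, 8 in cDC1 and 7 in cDC2. The Tet2 KO counts were then 29 in B cells, 14 in NK cells, 13 in migratory DCs, 5 in cDC1, 2 in neutrophils and 1 each in monocytes and cDC2. Without the term for the sorted fraction the Dnmt3a KO counts were 1544 in B cells, 16 in monocytes, 6 in ILC2, 4 in cDC2, 3 in neutrophils and 2 in cDC1, while T cells had 1 with either change. The Tet2 KO counts were 18 in B cells and 1 in cDC1 without that term.

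BC018473 was found in almost every class of the Dnmt3a KO libraries and near 0 in the others. It stood at 1482 plain CPM in Dnmt3a KO neutrophils of 24 weeks, where WT neutrophils held no UMI. It was at 385 and 207 in ILC2 cells of 30 and 24 weeks, at 185 and 165 in T cells and at 79.0 and 57.9 in B cells (pooled ratio 79.3, 45 to 154). The highest value in any other library was 5.52 in neutrophils, 13.3 in ILC2 cells, 4.31 in T cells and 1.48 in B cells. The edgeR count of 0 genes in Dnmt3a KO T cells therefore does not show a lack of difference there. Fibroblast-like cells of the Dnmt3a KO libraries had 0 in 18 cells at 24 weeks and 1 UMI in 69 cells at 30 weeks.

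**Figure D5:**
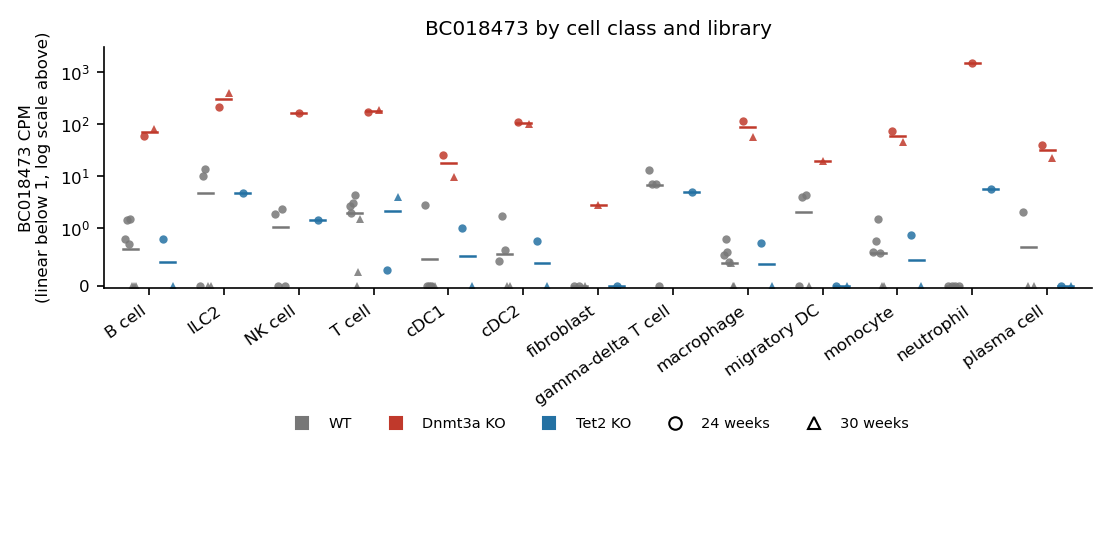
Plain CPM of BC018473 by cell class and library. Dnmt3a KO libraries reach 1482 in neutrophils, and no other library exceeds 13.3 in any class.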

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

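The tests of explanations in this part were all chosen after the results were seen, while the rules that picked the values in the first 2 paragraphs were planned.

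Among the 4 WT libraries of 24 weeks, WT-W 2 stood apart with 17.3% macrophages against 9.15% to 9.48% in the others. St6galnac2 stood apart in WT-D 2, at 0.256 normalised CPM with 0 in the others, a difference of 1 UMI. Of 43 sets of values tested in this way 2 stood apart, which is about the 1 in 20 that chance gives.

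The knockout effect differed between weeks in macrophages in 1 gene for Dnmt3a KO and 2 for Tet2 KO called by edgeR of 11682 (429 and 400 at an unadjusted p under 0.05). Cap1, an actin-binding protein gene, differed by 2.15 on the log2 scale between the Dnmt3a KO effects at 30 and 24 weeks (adjusted p = 0.0196): it was at 479 in the knockout and 104 to 112 in WT at 30 weeks, and at 175 and 167 to 187 at 24 weeks. Olfml3 differed by 4.10 for Tet2 KO (adjusted p = 0.00814), at 47.9 against 78.8 to 87.8 at 30 weeks and 2.14 against 45 to 80.1 at 24 weeks. The chemokine receptor gene Cxcr4 differed by -3.02 (adjusted p = 0.00814), at 46.5 against 202 to 283 at 30 weeks and 309 against 188 to 323 at 24 weeks. Each effect has 1 knockout library per week, assumed to vary like the other groups, so a difference of single libraries is not excluded and the counts do not show how many effects differ.

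BC018473 was higher in Dnmt3a KO macrophages than in WT, and was seen in other immune classes too. Free RNA spread through the droplets would give fibroblast-like cells the same level, but the upper counting bound there was 18.6 plain CPM, below the lowest lower bound of 51.0 in Dnmt3a KO macrophages. A background shared by all CD45.2 cells is argued against by macrophages of the CD45.2 WT libraries, whose highest upper bound was 1.59. The 3 neighbouring called pairs on chromosome 11 were more than random sets of 15 genes gave (0.0518 pairs on average, p = 0.0002 in a permutation test of 10000 draws). A segment of another strain near these genes may account for it, but 3 of the 10 genes tested there were called, which decides nothing without genotypes. A loss of methylation in cells that lack Dnmt3a stays open and was not tested.

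Immunoglobulin and B-cell transcripts were higher in Dnmt3a KO macrophages. RNA from other cells in the same library may be a source, since Igkc had a positive fold in 8 of 8 classes tested other than B and plasma cells. B cells counted within the macrophage class may add to it: taking away mixed subclusters removed 36.6% of the Mzb1 UMIs per macrophage in Dnmt3a KO 2, which leaves the rest open. Both Dnmt3a KO libraries held more plasma cells than the WT mean, so the composition of the tissue cannot be parted from either. No biological explanation was tested.

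The resident-like share was higher in all 4 knockout libraries than in all 7 WT libraries. Resident-like cells that all lack the Dnmt3a knockout, with BC018473 only from free RNA, are argued against: at least 10.6% of resident-like cells of Dnmt3a KO 1 held BC018473, against an upper bound of 7.81% from 1 of 69 fibroblast-like cells of the same library (median depths 4299 and 5079 UMIs), and at least 61.0% against 18.5% in Dnmt3a KO 2. The CD45.2 sort cannot be told apart from genotype at 30 weeks, where no WT library was CD45.2: with the term for the sort the log2 folds were 2.22 and 2.24, and without it 2.32 and 2.35, with an adjusted p of 0.111 and 0.00924 by edgeR. Sex went with genotype at 30 weeks too, and with sex as a term the folds were 2.69 and 2.19 (adjusted p = 0.110). An effect of either genotype stays open.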

How the results depend on the processing

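The sex, 24-week, cluster and resident-subcluster alternatives were chosen after the data were seen. The cause of each move below was not tested. Of 510 alternatives for 20 named gene results, 369 kept direction and side of the threshold, 74 lost the call, 67 gained it and 0 turned direction. Counts for Dnmt3a KO (main 15) were 95 with DESeq2's Wald test, 514 without the low-count filter, 26 without doublet removal, 2 with macrophages picked by markers, 9 when thinned, 73 without the sorted-fraction term, 6 with WT-condition controls, 1 with CD45.2 libraries, 33 with sex as a term, 29 with 24-week libraries (7 of them among the 15) and 36 without resident subclusters (8 to 45 with each library left out). Counts for Tet2 KO (main 1) were 2 with DESeq2 size factors, 24, 321, 0, 2, 4, 101, 0, 0, 5, 0 and 0 in that order, then 5 with mark f, 49 with the replicate block and 2 without mixed or single-library clusters (0 to 91). Counts for Dnmt3a KO against Tet2 KO (main 34) were 146 by Wald, 684 without the filter, 4 by markers, 5 thinned, 22 with mark f, 13 with the block, 7 with WT-condition controls, 1 with CD45.2, 0 with 24-week libraries and 59 without resident subclusters (8 to 155). WT-D against WT-W (main 0) gave 4 without the filter and 1 without the fraction term (0 to 0). Dnmt3a KO against WT-D (main 0) gave 8 by Wald, 17 without the filter, 1 without doublet removal, 1 by markers, 2 thinned, 9 without the fraction term and 1 with sex (0 to 4). Weeks (main 4794) gave 1969 by markers and 1776 thinned (3243 to 5223). The correlation of folds (main 0.438) was 0.501 with mark f, 0.316 without the fraction term, 0.227 with the block, 0.390 at an average log2 CPM of at least 5, 0.141 with split controls and 0.505 with sex (0.220 to 0.700). List calls (main 24) were 0 with an estimated correlation and 0 with fry's directional test (21 to 37), while its mixed test called 12. Class shares (main 1) were 0 with mark f, sex, 24-week libraries or resolution 2 (0 to 1). The exact permutation gave 0 too, but could give no other count, since the smallest p of its 20 arrangements is 0.05. State shares (main 0) were 2 without the fraction term and 1 with 24-week libraries (0 to 2). The block joined libraries of 1 condition or title mark within a week. Deviations correlated at 0.249 (WT-D 1, Dnmt3a KO 1), -0.458 (WT-T 1, Tet2 KO 1), -0.292 (WT-D 2, Dnmt3a KO 2), 0.193 (WT-W 2, Tet2 KO 2) and 0.127 (WT-W 3, WT-W 4). These values cannot decide whether the libraries were paired, since the fit ties together the deviations of the 2 libraries of each knockout. The main fits did not treat the libraries as paired, and pairing stays open. Under the block the adjusted p was 0.953 for C2, 0.0666 for BC018473, 0.250 for Lzts2 and 1.60e-04 for Apoc1. Where a left-out library leaves 1 per arm, the lone sample is assumed to vary like the other groups. The 86 macrophages of WT-T 1 (404008 UMIs) limit what the 30-week controls can show.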

Other observations

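The test of weeks against other splits was chosen after the result was seen, and the antibody, thymocyte and Y-transcript values below were looked up after the data were seen.

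Plasma cells with a detected heavy-chain segment in Dnmt3a KO libraries mostly used Ighv11-2. Ighv11-2, a heavy-chain segment typical of innate-like B-1 cells, was the segment of 172 of 207 plasma cells with a heavy-chain segment in Dnmt3a KO 2 (83.1%, exact 95% binomial interval 77.3% to 87.9%) and of 8 of 8 in Dnmt3a KO 1, out of 66 plasma cells there. It was the segment of 0 of the 6 to 38 such plasma cells in each of the other 9 libraries, which allows shares of up to 9.25% (Tet2 KO 2) to 45.9% (WT-D 1). The light chains differed between the knockout libraries: Igkv14-126 was that of 121 of 213 plasma cells in Dnmt3a KO 2 (56.8%), but of 10 of 64 in Dnmt3a KO 1 (15.6%), where 54 used Iglv1. Iglv1 also led in WT-T 1 (58 of 71), Tet2 KO 1 (41 of 58) and WT-W 1 (34 of 64). Among B cells Ighv11-2 was that of 16 of 36 in Dnmt3a KO 2 (44.4%) and of 1 of 1 in Dnmt3a KO 1. Each share comes from 1 library with no replicate test, and cells are not replicates.

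An unnamed cluster with Rag1, Ccr9 and Arpp21 among its leading genes, genes used by developing T cells, held at most 0.160% of any 30-week library. At 24 weeks it held 24.6% of WT-W 2, 15.7% of WT-W 4, 9.60% of WT-W 3, 9.07% of Tet2 KO 2, 4.37% of WT-D 2 and 2.46% of Dnmt3a KO 2. A subcluster of macrophages with Itgad and Adamdec1 among its leading genes held 19.0% of the macrophages of Dnmt3a KO 2 and 5.66% of those of WT-D 2. It held at most 0.209% of the macrophages of any other library.

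BC018473 was detected in 43 of 300 resident-like macrophages of Dnmt3a KO 1 (14.3%, exact 95% binomial interval 10.6% to 18.8%) and 17.3% of its other macrophages. In Dnmt3a KO 2 it was detected in 61 of 85 (71.8%, 61.0% to 81.0%) and 34.5%, with median depths of 8262 and 7369 UMIs. No WT resident-like cell held a UMI, but these are few: the 4 cells of WT-T 1 allow a share of up to 60.2%.

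Y-linked transcripts stood at 20.8, 50.1 and 20.2 CPM in the 3 CD45.1 libraries of 30 weeks, which express Xist, at 132 and 168 in the knockout libraries of 30 weeks, and at 0 to 0.0853 in the 24-week libraries that express Xist. In those CD45.1 libraries 157, 316 and 139 cells had a Y-linked UMI and none of Xist, and 18, 22 and 42 had both. Y-linked UMIs were in 6.61% to 15.6% of T cells and 46.7% to 60.0% of fibroblast-like cells there. Of the 35 splits of the 7 WT libraries into groups of 3 and 4, 1 gave as many genes as the split by week: the week split itself with 4794, while the highest other split gave 1041. With 35 splits, 1 is the fewest that can match, so chance is argued against but not excluded. The annotation and depth that differ with the week are not excluded either.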
